A study of Mus musculus with 12 samples.

How the data were processed

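Bulk RNA was sequenced from mouse endometrial epithelial organoids, which are cultures grown from the epithelium that lines the uterus. The 12 libraries form 4 groups of 3: wild type (WT) without estrogen, WT with estrogen, Esr1 knockout (KO) without estrogen and KO with estrogen. Per the labels, RNA was extracted with a Direct-zol kit, made into TruSeq mRNA libraries and sequenced as read pairs on an Illumina NovaSeq.

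The deposited files hold raw counts, whole numbers of reads per gene, with 1 file per library. Per the file headers, the authors counted reads with featureCounts 2.0.0 over the exons of RefSeq genes, summed by gene symbol, while their processing notes name version 2.0.3. The notes also name FastQC 0.11.7, Trim Galore 0.6.6, STAR 2.7.10b and the mouse genome build GRCm39. The recorded command counted each mate of a pair on its own, so the counts are reads and not fragments. It ignored the strand, and it counted neither reads that mapped to several places nor reads that overlapped several genes. Levels of near-identical gene families, such as Sprr2b and Sprr2e, Cstdc5 and its paralogs, or Krt14 and Krt16, are therefore uncertain. Of the 136 genes picked by the rules given below, all 136 were found in a RefSeq gene table of the older build GRCm38, and 46 overlapped another gene there. Their levels lack the shared reads and can include reads from the opposite strand, as for Dtx3l and Parp9, Tmod1 and Tstd2, Cdc20 and Elovl1, Stra6 and Ccdc33, Cryab and Hspb2, or Muc20 and Muc4. No gene positions are given, since no annotation of build GRCm39 was at hand.

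Library totals ran from 75654191 to 108665407 counted reads. A gene with 0 reads in all 3 libraries of a group was given a floor of 3 reads over the group, which is 0.0114 CPM (counts per 1e+06 counted reads) in untreated WT, 0.0112 in treated WT, 0.0116 in untreated KO and 0.00902 in treated KO. Folds against such a group are lower limits. With 1 to 3 reads over a group, the ratio of the groups is given with its exact 95% counting interval. Floors and intervals cover counting error only, and reads without molecular identifiers are not independent molecules. Replicates differed by far more than counting error, with a chi-square per degree of freedom of 48.8 to 321 between libraries of a group.

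The files list 26264 genes, of which 5461 had 0 reads in every library. Genes were kept by filterByExpr in edgeR 4.0.16 under R 4.3.3, with a minimum count of 10 and a minimum total of 15, which left 16465 genes. Counts were scaled by the trimmed mean of M values (TMM) and fitted with a quasi-likelihood model with robust estimates, in which the 12 libraries formed 4 groups that shared an estimate of the spread. CPM values are TMM-normalised, and errors of levels are SD over the 3 libraries of a group. The standard error (SE) of a log2 fold change was derived from the fold change and its F statistic. Tests were two-sided, and p-values were adjusted over all 16465 genes by the Benjamini-Hochberg method with a threshold of 0.05. Comparisons were KO against WT without estrogen, KO against WT with estrogen, estrogen against none in each genotype, and the interaction of genotype and estrogen. A gene counted as changed by genotype when it passed in both treatments with the same sign. The labels do not say whether the replicates of a group came from separate animals or cultures, nor whether treated and untreated libraries came from the same organoid lines. The p-values therefore measure only the spread between these libraries.

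Replicate numbers were checked for pairing by correlating, across genes, the libraries' deviations from their group means. Libraries of the same number correlated by 0.57, 0.50 and 0.41 in KO, the best match of the KO libraries. The correlations were -0.16, -0.16 and -0.39 in WT, so the numbers do not pair the WT libraries. WT libraries of other numbers correlated by 0.27, 0.46 and 0.40. With 3 libraries in a group, arbitrary numbers can give the best match by luck, so a pairing in KO is possible but not shown. The estrogen comparison of KO is therefore also given with replicate number within genotype as a block.

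Before the data were examined, 28 gene lists, the rule for naming genes, the comparisons and all alternative settings were fixed. The lists hold 782 entries, 736 distinct genes, and 42 genes stand in several lists. Only Dnai1 and Dnai2 of the ciliated list were not found under their symbols. Lists were tested with camera in limma 3.58.1, with a preset correlation of 0.01, which compares a list with all other genes, and adjusted over the 28 lists within a comparison. A list counted as changed by genotype when it passed in both treatments with the same sign, and the larger of both adjusted p-values is given. Each call was repeated with a correlation estimated from the data and with fry, which asks whether a list's genes move, on balance, in a direction. The list test of the interaction was added after the data were examined. Members were also adjusted over the list alone, which changed the genotype counts of 1 of the 28 lists, by 1 member.

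Named genes were, first, 11 genes of the receptor, hormone response and epithelial identity. Next came the 12 genes with the most positive and the 12 with the most negative mean log2 fold change. These had to pass in both genotype comparisons, to have a mean of at least 5 CPM, to have all 6 KO libraries on the same side of the 6 WT libraries, and to carry a proper name. Up to 10 genes past the threshold for estrogen or the interaction were to be named, and none passed in edgeR. Examples of a list are up to 4 of its members with the smallest p-values among those past the threshold, or up to 2 members given as values when none passed.

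The procedure was tested on simulated data in which 200 genes were changed 1.5-, 2- or 4-fold. Among simulated 4-fold changes, 72.3% to 83.3% were called in the comparisons of groups and 67.2% in the interaction. Among 1.5-fold changes, 28.4% to 40.9% and 7.46% were called. A simulated list of 30 genes raised 1.5-fold was found by camera in every comparison. Simulated genes varied independently, while the correlation estimated within real lists reached 0.776 (cell cycle genes, KO against WT without estrogen). The simulation therefore does not show how camera performs on correlated lists. Alternatives were other scalings, DESeq2 1.42.0, limma-voom, other count filters, fits on fewer libraries, replicate blocks, fits without robust estimates, other thresholds, summed treated and untreated libraries, and each library left out in turn.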

Results

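Reads per gene were counted in 12 libraries of mouse endometrial epithelial organoids, wild type (WT) or Esr1 knockout (KO), each without or with estrogen. Esr1 encodes estrogen receptor alpha, the receptor through which estrogen acts on the uterine lining. The series concerns the part this receptor plays in setting the identity of the uterine epithelium. Each of the 4 groups held 3 libraries. Counted reads averaged 94.3 ± 11.1 (SD, n = 3; in 1e+06 reads) in untreated WT, 96.2 ± 7.08 in treated WT, 79.4 ± 3.82 in untreated KO and 104.7 ± 3.48 in treated KO. The first principal component carried 92.3% of the variance and parted the genotypes. Levels below are group means ± SD (n = 3) in CPM (counts per 1e+06 counted reads). A gene is called higher or lower in KO only where edgeR passed it in both treatments with the same sign. In all 105 list examples, picked for their small p-values, the 6 KO libraries lay on the same side of the 6 WT libraries. The same was a condition for picking the 12 most positive and 12 most negative genes. The larger adjusted p-value of the genes so called ran up to 0.00346 among the examples and to 0.00639 among the genes picked outside the lists (edgeR).

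The target of the knockout was lower in all 6 KO libraries. Esr1 stood at 307.7 ± 50.2 CPM in untreated WT and at 16.4 ± 0.402 CPM in untreated KO. With estrogen it stood at 318.1 ± 33.5 and 19.7 ± 0.510 CPM. KO thus held 5.32% of the WT level without and 6.19% with estrogen. The log2 fold change was -4.23 ± 0.128 (SE; edgeR adjusted p = 1.34e-09) without and -4.01 ± 0.126 (edgeR adjusted p = 2.25e-09) with estrogen. The labels do not say which exons were deleted, so reads from the remaining exons cannot be set apart from intact transcript.

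The comparison of KO with WT asks which genes differ between the Esr1 genotypes in these organoids. Most measured genes differed, among them cytokeratins, cilia genes and hormone targets. Without estrogen, edgeR called 11811 of 16465 genes, 6206 higher and 5605 lower in KO. With estrogen it called 11655, 6043 higher and 5612 lower. Both treatments called 10686 genes with the same sign, 5612 higher and 5074 lower, and 2 genes with opposite signs. A change of at least 2-fold in both treatments was seen for 5862 genes, 4019 higher and 1843 lower. Groups were fully apart, 6 KO against 6 WT libraries, in 10699 genes or 65.0%, where chance gives 0.216% if the libraries are independent. Whether they are is not known, and the KO libraries match by number. The labels call the organoids endometrial, but they name no line or animal, and the uterine patterning genes Hoxa10 and Hoxa11 had only 8 and 10 reads over all 12 libraries. These values do not settle whether the lines of both genotypes had the same origin. Of the genes called in both, 381 had 0 reads in every WT library and 39 had 0 reads in every KO library. Scaling by library size alone moved the median log2 fold change by 0.226 without and 0.185 with estrogen. The share higher in KO among genes called in both was then 65.3% in place of 52.5%, so directions are relative to the scaling.

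Genes of the hormone response went both ways. Greb1, an early target of the estrogen receptor, was lower in KO at 0.321 ± 0.132 CPM against 159 ± 55.0 without estrogen, and at 0.404 ± 0.101 against 204 ± 54.7 with it. Pgr, the progesterone receptor, was lower at 22.8 ± 4.36 against 80.5 ± 28.0 CPM and at 28.4 ± 7.58 against 122 ± 37.7. Ltf, the iron-binding secretory protein lactoferrin, was higher at 15002 ± 2657 against 3105 ± 1692 CPM and at 19351 ± 5112 against 4438 ± 3277. Its log2 fold changes were 2.27 (edgeR adjusted p = 0.00436) and 2.12 (edgeR adjusted p = 0.00639). In the list of estrogen-response genes of the uterine epithelium, 17 of 40 tested members were higher in KO and 15 lower. Klk1, a kallikrein protease, was lower at 0.141 ± 0.0669 against 185 ± 18.9 CPM without estrogen. Sprr2e, a small proline-rich protein, was higher at 234 ± 5.17 against 0.149 ± 0.0790 CPM, and the mucin Muc1 was higher at 304 ± 17.2 against 78.9 ± 6.46 CPM. The list as a whole was not called (camera adjusted p = 0.519). Among 25 steroid receptors and cofactors, 6 were higher and 12 lower, and the list was not called (camera adjusted p = 0.0746). Its lower members included Esr1 and the steroid 5-alpha-reductase Srd5a1 (84.4 ± 9.11 against 608 ± 56.8 CPM).

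**Figure D1:**
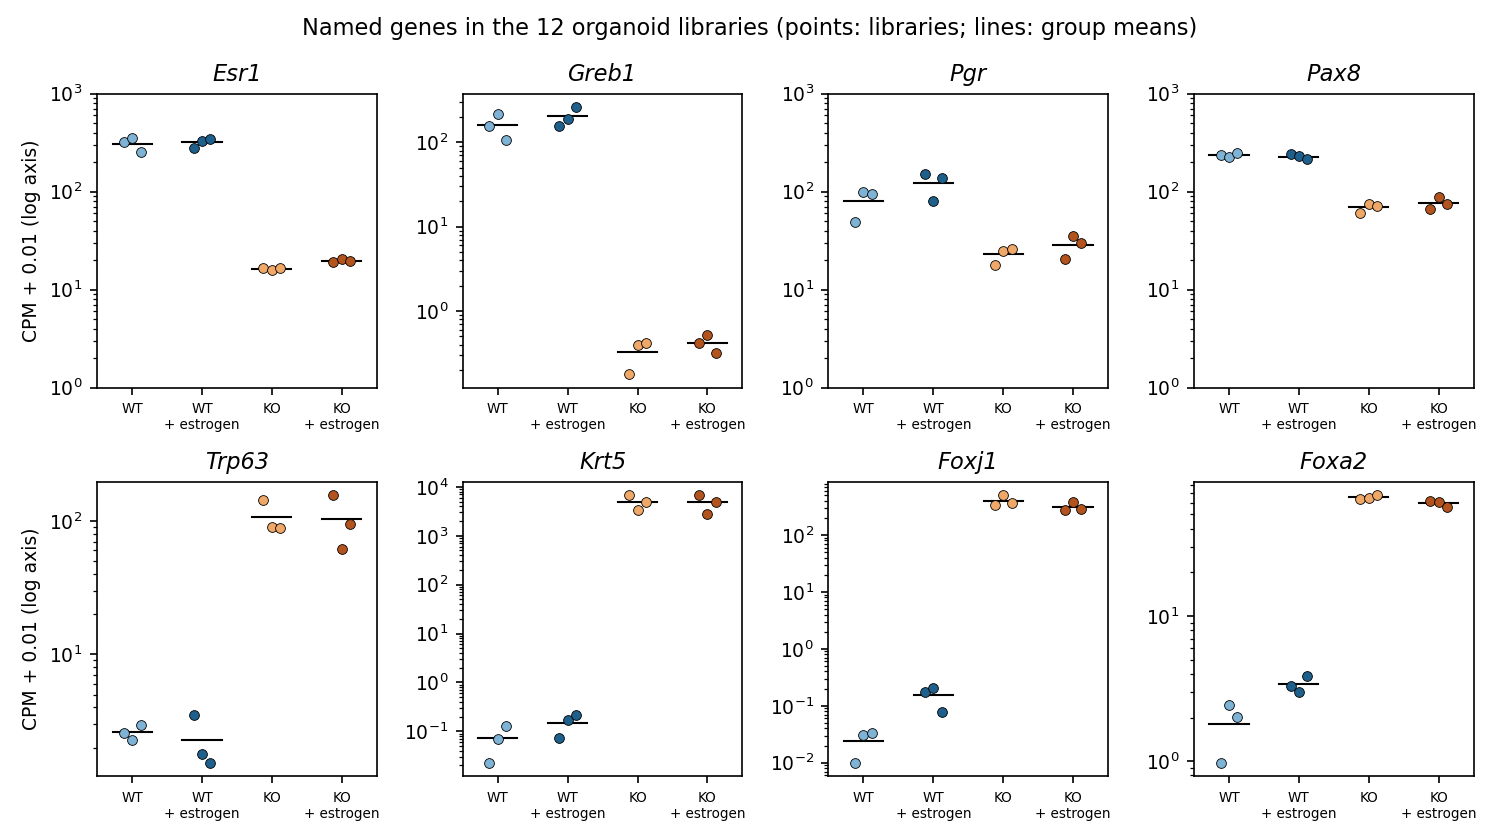
CPM plus 0.01 (log axis) of 8 genes in the 4 groups, with a point per library and a line at each group mean. Esr1, Greb1, Pgr and Pax8 lie lower in KO, while Trp63, Krt5, Foxj1 and Foxa2 lie higher, with and without estrogen.

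Genes of stratified epithelium were higher in KO. Krt5, a keratin of basal cells, stood at 5006 ± 1671 CPM in untreated KO against 0.0631 ± 0.0516 in untreated WT, and at 4825 ± 1987 against 0.141 ± 0.0720 with estrogen. Trp63, the transcription factor of basal cells, stood at 107 ± 30.7 against 2.60 ± 0.345 CPM without and at 104 ± 47.6 against 2.26 ± 1.07 with estrogen. Of 30 tested basal cell markers, 22 were higher and 4 lower (camera adjusted p = 1.21e-06; adjusted p = 0.422 with an estimated correlation). Higher examples without estrogen were podoplanin Pdpn (101 ± 11.6 against 0.211 ± 0.133 CPM), galectin Lgals7 (317 ± 72.5 against 0.0367 ± 0.0329 CPM) and Snai2, a transcriptional repressor (20.0 ± 4.00 against 0.0145 ± 0.0126 CPM). Of 42 squamous differentiation genes, 41 were higher and 0 lower (camera adjusted p = 1.42e-10; adjusted p = 0.422 with an estimated correlation). Krt16 stood at 2107 ± 559.8 against 0.0786 ± 0.0594 CPM, Krt13 at 1277 ± 393 against 0.0422 ± 0.0526 CPM, and envoplakin Evpl, a part of the cornified envelope, at 237 ± 50.04 against 18.2 ± 1.38 CPM.

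Genes of multiciliated cells were the list with the smallest p-value of the 28. Of 42 tested ciliated cell genes, 41 were higher in KO and 0 lower (camera adjusted p = 7.79e-44; adjusted p = 0.295 with an estimated correlation). Foxj1, the master regulator of motile cilia, stood at 397 ± 86.3 CPM in untreated KO against 0.0145 ± 0.0126 in WT, and at 316 ± 60.0 against 0.142 ± 0.0660 with estrogen. The axonemal dynein Dnah5 stood at 181 ± 46.0 against 0.0502 ± 0.0121 CPM without estrogen, tektin Tekt1 at 48.4 ± 12.4 against 0.0303 ± 0.0242 CPM, and Zmynd10, which helps assemble dynein arms, at 42.7 ± 9.54 against 0.70 ± 0.0897 CPM. Foxa2, the transcription factor of uterine glands, was higher at 65.5 ± 1.91 against 1.80 ± 0.749 CPM without and at 59.6 ± 2.66 against 3.39 ± 0.438 CPM with estrogen. Of 16 glandular markers, 8 were higher and 2 lower, with Cxcl15 higher (22.5 ± 6.95 against 0.0631 ± 0.0380 CPM) and Gpx3 lower (16.6 ± 2.06 against 7103 ± 3744 CPM). The glandular list was not called (camera adjusted p = 0.0769), but was called without WT untreated replicate 1 (0.0199) or without KO untreated replicate 1 (0.0370).

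Of 19 luminal markers, 11 were higher in KO and 5 lower (camera adjusted p = 0.0442; adjusted p = 0.422 with an estimated correlation). Histidine decarboxylase Hdc (200.1 ± 14.8 against 0.565 ± 0.139 CPM) was higher and the growth factor receptor Fgfr2 (31.3 ± 4.24 against 383 ± 31.2 CPM) lower. Wnt11 was higher at 74.1 ± 14.5 CPM, against 2 reads over the untreated WT group. The luminal call was lost with library size alone (camera adjusted p = 0.0780), with at least 1 CPM (0.0522), and without WT untreated replicate 2 (0.0791), KO treated replicate 1 (0.0534) or KO treated replicate 2 (0.0638). The ligand Wnt7a, made by the luminal epithelium, had a log2 fold change of 0.86 (edgeR adjusted p = 0.365) without and 2.18 (edgeR adjusted p = 0.0394) with estrogen, so it was not called in both. The stem cell marker Lgr5 did not pass in either treatment (log2 fold changes 0.18 and 0.61; edgeR adjusted p = 0.784 and 0.346). Of 28 simple epithelium identity genes, 4 were higher, 10 lower and 14 not called in both treatments (camera adjusted p = 0.519). The protease inhibitor Spint1 was lower (256 ± 24.1 against 989 ± 44.2 CPM), as was the transcription factor Grhl2 (67.1 ± 1.88 against 129 ± 12.9 CPM). The other examples, Tjp3 and Esrp1, were higher in KO, by 2.45- and 1.83-fold without estrogen and by 2.15- and 1.79-fold with it.

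**Figure D2:**
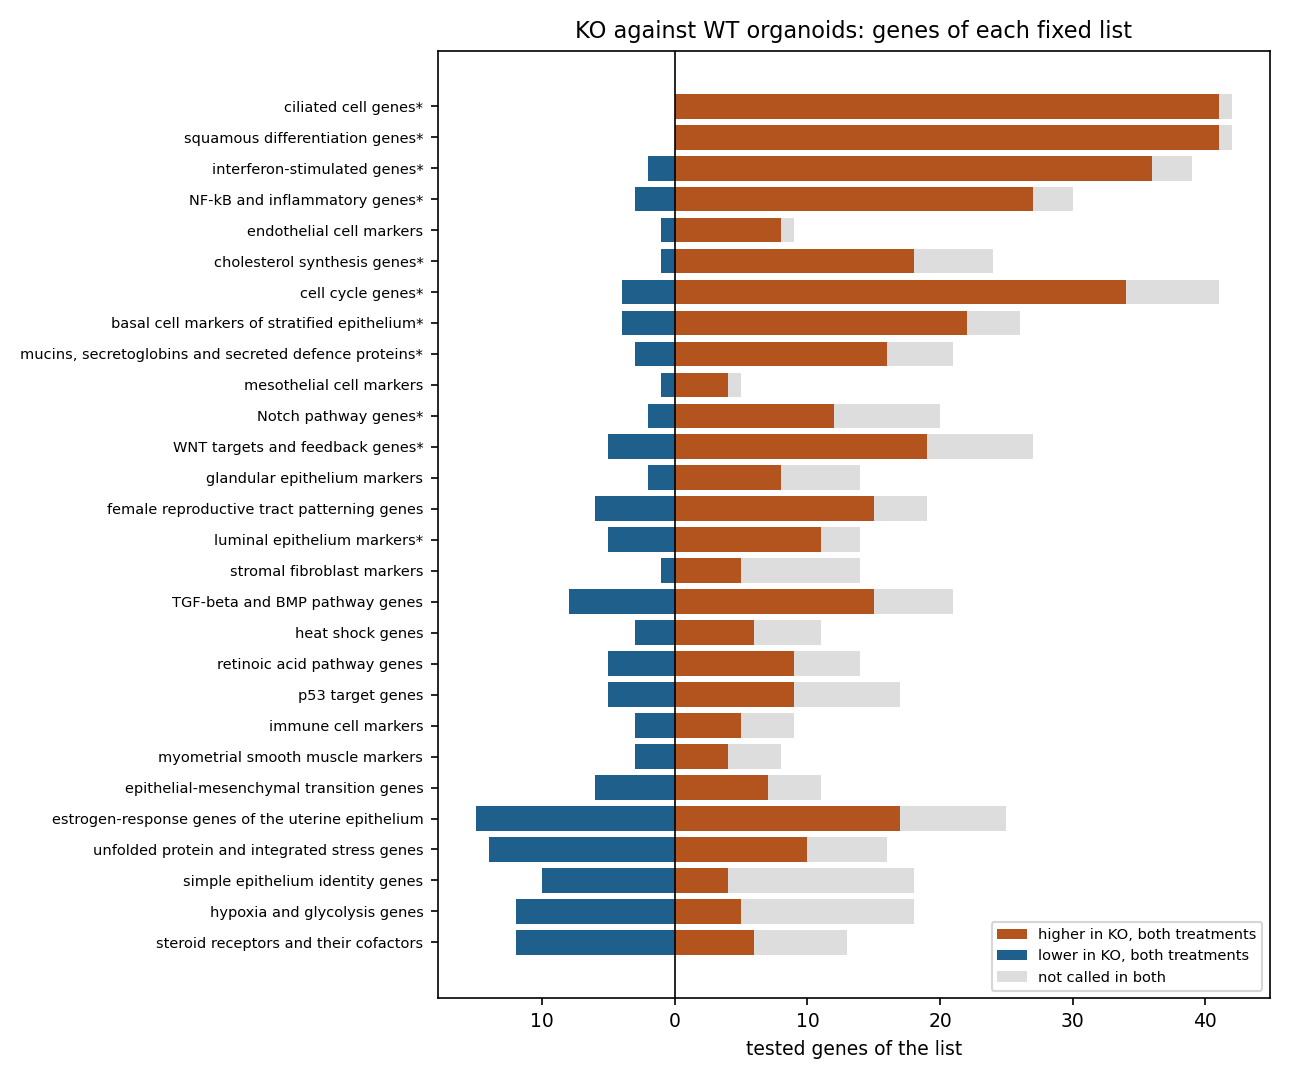
Members of the 28 gene lists called higher in KO in both treatments (bars to the right), called lower in both (bars to the left) or not called in both (grey), as numbers of genes. Stars mark the 11 lists that camera called, and ciliated and squamous lists show 41 higher and 0 lower members each.

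Patterning genes of the female reproductive tract were mixed, with 15 of 25 higher and 6 lower (camera adjusted p = 0.227). Pax8, a factor of the Müllerian duct lineage, was lower at 68.9 ± 7.13 against 236 ± 12.0 CPM without and 76.3 ± 11.4 against 228 ± 15.0 CPM with estrogen. Meis1 was higher (96.2 ± 5.83 against 25.8 ± 2.50 CPM). Of 32 WNT targets and feedback genes, 19 were higher and 5 lower (camera adjusted p = 0.0167; adjusted p = 0.422 with an estimated correlation). The secreted WNT inhibitor Sfrp1 was higher (12.8 ± 0.60 against 0.202 ± 0.0431 CPM) and the receptor Tnfrsf19 lower (9.76 ± 0.0271 against 225 ± 56.1 CPM). Of 22 Notch pathway genes, 12 were higher and 2 lower (camera adjusted p = 0.0324; adjusted p = 0.392 with an estimated correlation), with the receptor Notch1 at 112 ± 18.6 against 9.65 ± 2.66 CPM and its ligand Jag2 at 88.1 ± 31.8 against 3.33 ± 0.0659 CPM. Of 19 retinoic acid pathway genes, 9 were higher and 5 lower (camera adjusted p = 0.906). Aldh1a2, which makes retinoic acid, was lower at 0.635 ± 0.160 against 2110 ± 227 CPM, and Lrat, which stores retinol as esters, at 0.130 ± 0.0629 against 390.2 ± 102.4 CPM. Among 29 TGF-beta and BMP pathway genes, 15 were higher and 8 lower (camera adjusted p = 0.692), with the ligand Tgfb2 lower (46.0 ± 14.8 against 1454 ± 204 CPM) and the matrix protein Ltbp2 higher (229 ± 10.4 against 0.95 ± 0.194 CPM).

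Proliferation and defence genes were higher in KO. Of 45 cell cycle genes, 34 were higher and 4 lower, or 35 and 4 when adjusted over the list alone (camera adjusted p = 4.31e-04; adjusted p = 0.780 with an estimated correlation). Cenpf, a kinetochore protein, stood at 47.3 ± 6.98 against 6.18 ± 1.18 CPM, and Cdc20, an activator of the anaphase-promoting complex, at 60.2 ± 10.0 against 12.2 ± 2.15 CPM. Of 41 interferon-stimulated genes, 36 were higher and 2 lower (camera adjusted p = 7.16e-07; adjusted p = 0.422 with an estimated correlation), such as Parp14 (82.4 ± 6.55 against 23.9 ± 3.25 CPM). Of 33 NF-kB and inflammatory genes, 27 were higher and 3 lower (camera adjusted p = 0.00156; adjusted p = 0.492 with an estimated correlation). The chemokine Ccl20 (72.1 ± 5.05 against 2.56 ± 0.399 CPM) and the adhesion molecule Icam1 (159 ± 13.8 against 3.35 ± 0.364 CPM) were higher, and the growth factor Csf1 was lower (20.6 ± 1.56 against 3203 ± 575 CPM).

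Of 24 mucins, secretoglobins and secreted defence proteins, 16 were higher and 3 lower (camera adjusted p = 0.0415; adjusted p = 0.508 with an estimated correlation). Dmbt1, a scavenger receptor of mucosal defence, was higher (511 ± 216 against 0.198 ± 0.175 CPM), and complement C3 lower (2306 ± 359 against 18633 ± 3736 CPM). This call was lost with library size alone (camera adjusted p = 0.0814) and without WT treated replicate 1 (0.0513). Of 25 cholesterol synthesis genes, 18 were higher and 1 lower (camera adjusted p = 0.0442; adjusted p = 0.780 with an estimated correlation). Hmgcs1, an early enzyme of the pathway, was higher (322 ± 35.8 against 87.2 ± 5.25 CPM). The cholesterol call was lost with replicate number as a block (camera adjusted p = 0.0880). It was also lost without any of the 6 WT libraries, KO untreated replicate 1, KO treated replicate 1 or KO treated replicate 3 (0.0518 to 0.0724).

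The lists of the stress responses, hypoxia and glycolysis, and p53 targets were not called for genotype. Among 30 genes of the unfolded protein and integrated stress response, 10 were higher and 14 lower (camera adjusted p = 0.241), with the chaperone Hyou1 lower (222 ± 13.3 against 676 ± 66.1 CPM). Among 14 heat shock genes, 6 were higher and 3 lower (camera adjusted p = 0.678), with Hsp90aa1 higher (1524 ± 229.8 against 363 ± 37.4 CPM) and Cryab lower (55.6 ± 6.13 against 291 ± 70.0 CPM). Among 30 hypoxia and glycolysis genes, 5 were higher and 12 lower (camera adjusted p = 0.519), with the glucose transporter Slc2a1 lower (154 ± 22.7 against 725 ± 95.0 CPM). Among 22 p53 targets, 9 were higher and 5 lower (camera adjusted p = 0.519), with Perp, which is also a protein of desmosomes, higher (1573 ± 225 against 215 ± 20.1 CPM).

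Camera called none of the lists of stromal, myometrial, immune, endothelial and mesothelial markers, apart from the stromal list under another count filter. Of 15 tested stromal fibroblast markers, 5 were higher and 1 lower (camera adjusted p = 0.241, but 0.0173 and called with at least 1 CPM). The matrix protein Postn was higher at 962 ± 145 CPM against 0.0232 ± 0.0401, and the filament protein Vim stood at 6.73 ± 0.952 against 0.122 ± 0.0546 CPM. The lower member, the collagen Col6a3, was 390-fold lower in KO without and 175-fold lower with estrogen. Of 11 myometrial smooth muscle markers, 4 were higher and 3 lower (camera adjusted p = 0.990). Of 12 immune cell markers, 5 were higher and 3 lower (camera adjusted p = 0.743), with Cd74 higher (17.8 ± 1.33 against 0.0996 ± 0.0691 CPM) and Csf1r lower (0.309 ± 0.241 against 31.3 ± 10.1 CPM). Ptprc had 0 reads in untreated KO against 6.41 ± 1.14 CPM in untreated WT, at least 554-fold lower. Of 10 endothelial markers, 8 were higher and 1 lower (camera adjusted p = 0.0746), with Ramp2 at 21.3 ± 2.07 against 0.694 ± 0.177 CPM. Of 6 mesothelial markers, 4 were higher and 1 lower (camera adjusted p = 0.906), where the lower member was Aldh1a2. Of 17 genes of the epithelial-mesenchymal transition, 7 were higher and 6 lower (camera adjusted p = 0.692), with the matrix protein Tnc higher (49.9 ± 13.8 against 0.218 ± 0.240 CPM) and the integrin Itgav lower (136 ± 14.4 against 737 ± 75.4 CPM).

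None of the 11 calls was kept with an estimated correlation. The median and the mean log2 fold change lay above 0 in the estrogen-response, retinoic acid and mesothelial lists, where camera's direction was lower. In the steroid receptor list the mean lay above 0, while the median and camera's direction were lower. Camera's direction in the myometrial list was higher without and lower with estrogen.

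The 12 genes with the most positive mean change were Cstdc5, Krt14, Krtdap, Postn, Rptn, Pitx1, Ccdc153, Calm4, Lrrc23, Sptssb, Reg3g and Krt5. Krt14, the partner of Krt5 in basal cells, stood at 2081 ± 495 CPM in untreated KO against 3 reads over untreated WT, a ratio of 182020 with a 95% counting interval of 62284 to 882634. With estrogen it was at least 164729-fold higher, against 0 reads in WT. The transcription factor Pitx1 had 0 reads in all 6 WT libraries and was at least 9619.95-fold higher in KO without and at least 10099.5-fold higher with estrogen. The cilia gene Lrrc23 was likewise at 0 in WT and at least 9425-fold and 6831-fold higher in KO. The 12 with the most negative change were Aqp8, Tmod1, Car4, Tmem229a, Cys1, Cd36, Adam33, Havcr1, Cuzd1, Inmt, Asic2 and Nptx1. The water channel Aqp8 stood at 2328 ± 236 CPM in untreated WT against 0.0452 ± 0.0595 in KO, and at 2148 ± 219 against 0.214 ± 0.122 with estrogen. The membrane protein Havcr1 stood at 1830 ± 318 against 0.265 ± 0.171 CPM and at 1417 ± 444 against 0.556 ± 0.320 CPM. The carbonic anhydrase Car4 had 0 reads in all 6 KO libraries and was at least 1197-fold lower without and at least 938-fold lower with estrogen.

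The comparison of treated with untreated WT asks which genes respond to estrogen where the receptor is present. The labels state that the organoids of neither genotype responded to it. In WT, edgeR called 0 of 16465 genes, with 883 at an unadjusted p under 0.05 where 823 were expected, while DESeq2 called 69 and limma-voom 0. Esr1, Pgr and Greb1 had means of 307.7 and 318.1, 80.5 and 122, and 159 and 204 CPM without and with estrogen, none past the threshold in edgeR. Camera called 7 lists. Higher with estrogen were glandular markers (adjusted p = 0.00175; adjusted p = 0.154 with an estimated correlation), and cholesterol synthesis (adjusted p = 3.43e-04), ciliated (adjusted p = 0.0166), mucin (adjusted p = 0.0266) and p53 target genes (adjusted p = 0.0228). Interferon-stimulated (adjusted p = 1.89e-04) and hypoxia genes (adjusted p = 0.0141) were lower. For these 6 lists the adjusted p was 0.981 with an estimated correlation.

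Among members of fixed lists in WT, edgeR passed 8 genes when adjusted over the list alone and none over all genes. DESeq2 passed all of these but Myb over all genes, from Cdkn2a (adjusted p = 1.88e-04) to Wnt5a (adjusted p = 0.0496). Without WT treated replicate 1, edgeR passed Cdkn2a, Wnt5a and Agr2 over all genes (adjusted p = 0.00219, 0.0475 and 0.0492). Foxa2 went from 1.80 ± 0.749 to 3.39 ± 0.438 CPM (log2 fold change 0.91; edgeR p adjusted over the list alone = 0.0497, adjusted over all genes = 0.617). Wnt5a went from 58.3 ± 11.2 to 97.2 ± 25.1 CPM (0.74; 0.0388 and 0.614), and Myb, an early regulator of multiciliated cells, from 8.85 ± 1.49 to 13.8 ± 1.83 CPM (0.64; 0.0320 and 0.587). The others were Foxj1 with 4 against 38 reads, Vim, Mvd, Agr2 and Cdkn2a. Of the ciliated members, 31 of 42 lay under 1 CPM in WT. Without WT treated replicate 1, edgeR called 54 genes for estrogen in WT, 45 higher and 9 lower, and without WT untreated replicate 3 it called 1, Tmem181b-ps. With replicate number within genotype as a block it called 7, although the numbers do not pair the WT libraries.

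The same comparison in KO asks what estrogen does where the receptor was deleted. In KO, edgeR called 0 of 16465 genes, with 411 at an unadjusted p under 0.05, while DESeq2 called 20 and limma-voom 0. With replicate number within genotype as a block it also called 0. Camera called 6 lists. Ciliated cell genes were lower with estrogen, with 42 of 42 below 0 and a median log2 fold change of -0.29 (camera adjusted p = 6.96e-14; adjusted p = 0.379 with an estimated correlation). With the block this call held at camera adjusted p = 4.89e-32 and at adjusted p = 0.0219 with an estimated correlation. The block assumes a pairing by number that the labels do not give. Lrrc23 went from 107 ± 22.5 to 76.3 ± 9.37 CPM and Deup1 from 47.2 ± 4.95 to 37.3 ± 4.01 CPM, neither past the threshold in edgeR. Hypoxia and glycolysis genes were higher, with 30 of 30 above 0 and a median of 0.14 (camera adjusted p = 7.28e-08; adjusted p = 0.451 with an estimated correlation). Also higher were cholesterol synthesis genes (camera adjusted p = 6.72e-06; adjusted p = 0.451 with an estimated correlation), the unfolded protein response (3.77e-05; 0.28), estrogen-response genes (2.08e-04; 0.28) and the retinoic acid pathway (0.00116; 0.114), with both p-values in the same order. With the block, these 5 lists were also called by camera, and none with an estimated correlation (adjusted p = 0.497). The block added calls of simple epithelium genes (camera adjusted p = 0.0451), mucins (0.0122) and p53 targets (0.0471), all higher (adjusted p = 0.497, 0.540 and 0.604 with an estimated correlation).

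In KO, edgeR passed some members of fixed lists when adjusted over the list alone, and none over all genes. Among those named here, DESeq2 passed Lrat, Dhrs9 and Padi2 over all genes (adjusted p = 1.63e-05, 0.00324 and 0.0492). Lrat went from 0.130 ± 0.0629 to 0.735 ± 0.362 CPM (log2 fold change 2.48; edgeR p adjusted over the list alone = 0.00378, adjusted over all genes = 0.876). Dhrs9, a retinol dehydrogenase, went from 4.97 ± 1.06 to 12.3 ± 1.04 CPM (1.3; 0.00378 and 0.876). The deiminases Padi1 and Padi2 went from 56.4 ± 16.6 to 101 ± 15.2 CPM and from 2.95 ± 1.40 to 7.02 ± 1.85 CPM (0.85 and 1.25; both 0.0489 and 1). Synpo2 went the other way, from 24 to 8 reads. Without KO untreated replicate 3, edgeR called 4 genes, Bcat1, Tmem213, Arsj and Pcdh17, all higher.

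**Figure D3:**
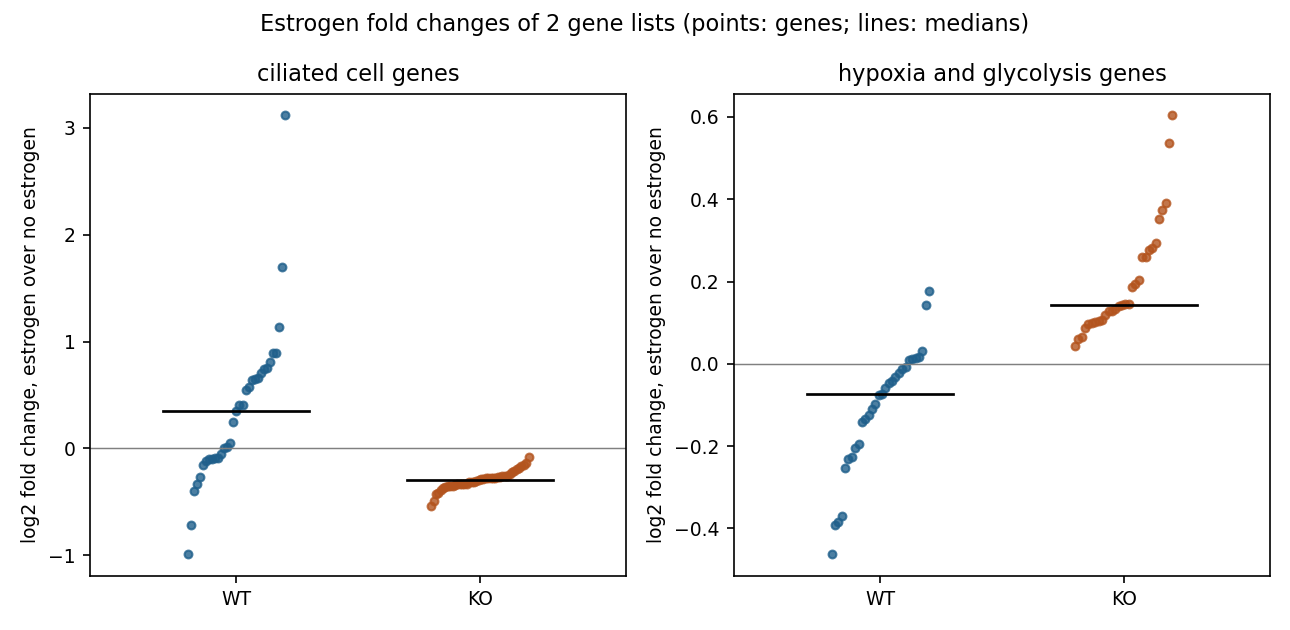
Log2 fold change with estrogen of ciliated cell genes and of hypoxia and glycolysis genes in WT and KO, with a point per gene and a line at the median, for genes with over 3 reads in both groups. The 42 ciliated genes of KO lie below 0 and the 30 hypoxia genes of KO above it, while 21 of 33 ciliated and 7 of 30 hypoxia genes lie above 0 in WT.

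The interaction asks whether the response to estrogen differed between the genotypes. Here edgeR called 0 of 16465 genes, with 726 at an unadjusted p under 0.05, while DESeq2 called 27 and limma-voom 0. Ciliated cell genes had a lower and hypoxia genes a higher response in KO than in WT (camera adjusted p = 9.44e-08 for each; adjusted p = 0.751 with an estimated correlation). With replicate number within genotype as a block, the values were camera adjusted p = 8.07e-10 and 2.70e-08 (adjusted p = 0.223 and 0.958 with an estimated correlation), and glandular markers also had a lower response (0.0291; 0.958). The numbers do not match the WT libraries, so for the WT part of the interaction these blocked values rest on a pairing that the libraries do not show. Without WT treated replicate 1, edgeR called 6 genes, Ltbp2, Tshz2, Cdkn2a, Sulf2, Ogdhl and Stxbp6, all with a lower response in KO. With the block it called 4 genes, Ccnd2, Penk, Anpep and Vnn1, also with a lower response in KO, under the same limit of pairing.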

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

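The splits of the estrogen comparisons and of the interaction, and the list test of the interaction, were chosen only after the results were seen. Ciliated cell genes and hypoxia and glycolysis genes differed between the genotypes in their change with estrogen (camera adjusted p = 9.44e-08 for each; adjusted p = 0.751 with an estimated correlation). The ciliated list went lower in KO (median log2 fold change -0.29) and the hypoxia list higher (0.14), while 31 of the 42 ciliated members lay under 1 CPM in WT. All treated KO libraries were larger than all untreated ones, so these shifts cannot be told apart from depth. Interaction calls of single genes numbered 0 in edgeR, and the highest count among the other of 100 splits was 13. A real count of 0 fixes the comparison with other splits in advance, so these splits say nothing about chance.

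Most genes differed between KO and WT, which the design cannot credit to the deletion alone. The planned test of library depth looked for opposite directions in the 2 treatments. KO libraries were smaller than WT without estrogen. With estrogen they were larger on average, but the libraries of the genotypes overlapped in size. Of the genes called in either treatment, 99.3% had the same sign in both. Counts were scaled for library totals before the fit, so a depth effect need not appear as opposite signs. That test therefore cannot decide. Without the 50 most abundant genes, 10644 genes were still called in both treatments. Both fits were scaled by TMM, which trims extreme genes, so the count was likely to stay and this test decides little. Those 50 genes held 16.0% of WT and 13.2% of KO reads, so they did not take most of the counts. Also open is a batch or organoid line shared by all libraries of a genotype. It cannot be told apart from the deletion, because the labels give 0 fields for a batch, date or line.

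With single libraries as the units, only the real split of the 100, 1 split, reached the 10686 genes called in both treatments. The highest other split called 0. The labels do not say whether replicates are separate animals or lines, so these splits cannot exclude chance differences between lines. The KO libraries match by number (correlations of 0.57, 0.50 and 0.41), which may reflect pairs or luck. Splits that keep such pairs together were not counted on their own. For the single treatments the real counts were 11811 and 11655 and the highest other split called 0, with 10 splits each, too few for a share under 0.05.

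Basal, squamous and ciliated genes were higher in KO, and a different mixture of cell types at the start of the culture may account for it as well as a change of the cells in culture. Cells of the cervix or vagina would bring Hoxa13 and Hoxd13, but these had 2 reads over all 12 libraries. The planned bound, neither gene called higher in KO, could not be tested, since both genes failed the count filter. Such cells are therefore not excluded. The uterine patterning genes Hoxa10 and Hoxa11 were nearly absent too (8 and 10 reads), so missing reads of these genes say little about origin. Cells of the oviduct would bring Ovgp1, Pax2 and Pax8, whose mean log2 fold change was -1.32 (-1.15, -1.14 and -1.68). With so few Hoxa10 and Hoxa11 reads that test could not be run as planned, and Ovgp1 depends on estrogen action while WT organoids also express Pax2 and Pax8, so both sources stay open beside the deletion itself, which was not tested against them.

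In edgeR no gene passed for estrogen in either genotype, where DESeq2 called 69 genes in WT and 20 in KO, and the labels state a lack of response. Whether differences between organoid lines hide a response in KO stays open. The block on replicate numbers, whose pairing in KO is not certain, still called 0 genes there. It raised the genes at an unadjusted p under 0.05 from 411 to 668. It also brought the ciliated list to camera adjusted p = 0.0219 with an estimated correlation. Power under the block was not simulated, so the count of 0 cannot decide. Low power may hide modest responses, since 83.3% of simulated 4-fold changes were called in WT but 28.4% of 1.5-fold ones, so the planned bound of 80% at 4-fold says nothing of smaller changes and rests on simulated ones. Mixed labels stay open, since another split of the 6 WT libraries called 45 genes where the real split called 0, which points to a structure among these libraries, and the bound of 100 genes assumed a broad response. Of the 10 splits of the 6 libraries of a genotype, the highest other called 45 genes in WT and 1 in KO, and the real counts of 0 leave nothing to test against chance.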

How the results depend on the processing

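Esr1 was lower in KO in all alternatives, with mean log2 fold changes of -3.92 to -4.19 (-4.12 reported). Of the values of named genes, 824 kept their direction and their side of the threshold, 0 reversed and 1 newly passed, the Wnt7a log2 fold change with treated and untreated libraries summed (1.45, adjusted p = 0.0257). Counts called in both treatments were 9009 to 10949 over the alternatives other than a 2-fold limit and 10103 to 10548 with a library left out. Summing treated and untreated libraries leaves a single genotype comparison, which called 12650 genes. Requiring a 2-fold change gave 6534 genes without estrogen, 6359 with estrogen and 5862 in both, by construction. DESeq2 called 69 genes for estrogen in WT, 20 in KO and 27 for the interaction, and the cause was not tested. A block of replicate number within genotype called 7, 0 and 4, and the cause was not tested. Without a library, counts ran from 0 to 54 in WT, 0 to 4 in KO and 0 to 6 for the interaction. Of the 11 lists called for genotype, camera with an estimated correlation kept 0, and fry, which asks another question, called 22 of all 28 lists. Other settings called 9 to 11. Without a block, fry kept none of camera's list calls for estrogen or the interaction. Its smallest adjusted p among those lists was 0.177 in WT, 0.265 in KO and 0.845 for the interaction. With the block within genotype, fry passed the ciliated list in KO (adjusted p = 0.00555) and in the interaction (fry adjusted p = 0.0373). WT libraries did not match by number, and the highest correlations there were 0.27, 0.46 and 0.40 between untreated and treated libraries of other numbers. List tests were not rerun under DESeq2, limma-voom, contrast-only fits or other thresholds. A fit on fewer libraries was not run for the interaction, nor the block within genotype for the genotype comparisons, which it absorbs. Depth limits genes near 3 reads per group.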

Other observations

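Homeobox genes of 1 cluster were read in both genotypes. The 10 Hoxb genes held 349241 reads over the 12 libraries, with Hoxb6 at 104 ± 7.47 CPM in untreated WT and 81.4 ± 7.26 CPM in untreated KO (SD, n = 3). The 11 Hoxa genes held 172 reads, the 9 Hoxc genes 18 and the 9 Hoxd genes 137. Hoxa10 and Hoxa11, patterning genes of the uterus, had 8 and 10 reads. The tissue origin of the lines, which the labels give as endometrial, was not tested in either genotype. The intermediate-chain dyneins Dnai1 and Dnai2 are listed as Dnaic1 and Dnaic2 in the files. Dnaic1 had 0 reads in untreated WT against 26.4 ± 8.62 CPM in untreated KO, and Dnaic2 stood at 67.6 ± 12.8 CPM in untreated KO against 2 reads over untreated WT.

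Some genes were picked here after their values were seen, as those that the replicate block called for estrogen in WT or that leaving out a library called in KO. In WT without and with estrogen, Ccnd2 stood at 0.915 ± 0.506 and 3.85 ± 2.19 CPM, Penk at 0.925 ± 0.479 and 9.51 ± 5.86 CPM, and Anpep at 0.556 ± 0.338 and 4.19 ± 2.58 CPM. In KO, Ccnd2 stood at 122 ± 51.6 and 134 ± 46.8 CPM, Penk at 7.35 ± 1.72 and 7.88 ± 3.40 CPM, and Anpep at 330.1 ± 15.0 and 424 ± 32.6 CPM. Bcat1 went from 6.496 ± 2.05 to 18.3 ± 2.01 CPM in KO, against 1236 ± 116 and 1313 ± 140 CPM in WT.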
